A study of Homo sapiens with 16 samples.

How the data were processed

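RNA from HepG2 cells transfected with control siRNA or HCF-1 siRNA was made into stranded mRNA libraries, per the labels' protocols, with 2 rounds of transfection. The authors deposited 1 table of normalized counts, a signal per Ensembl gene and library, made with cutadapt 1.4.2, STAR 2.4.1d, featureCounts 1.4.4 and DESeq2 1.16.1 on build hg19, per the submitters' processing notes. The annotation release, the strand setting and any filter are not given in the sources used here. Every deposited value was a whole multiple of 1 step per library (100% of values, within 0.001 read), so whole reads were recovered by dividing by that step. The step corresponded to size factors 1.0411 to 1.048 times those recomputed from the 16 libraries. All columns of per-library values were used, and 1 column was matched to its library although its name lacks a digit the others have. No pair of libraries agreed within sampling noise.

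For the comparison, 8 HCF-1 siRNA libraries were set against 8 control siRNA libraries with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend and robust options) on log2(deposited normalized count + 1), for genes with a mean of 10 or more. Calls had a Benjamini-Hochberg adjusted p under 0.05, and a second count required a 1.5-fold change. The pseudocount understates the change of low genes. Gene lists were tested with camera at a preset correlation of 0.01 and without a variance trend, its default, with adjustment over 28 lists, and again with an estimated correlation. Members were matched by symbol, then by older symbols, and the Ensembl gene with the highest mean was taken where a symbol repeats. The 29 lists, the tests, the rule for named genes and most alternatives were fixed before the data were examined.

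Named genes were HCFC1, the 8 largest increases and 8 largest decreases among called genes with a group mean of at least 100 and groups that do not overlap, up to 3 called members of largest change per list with a group mean of at least 50 in either group, or the member with the highest mean where none passed, and HCFC2, OGT, THAP11, ZNF143, GABPA, BAP1, INSR, IGF1R, IRS1, IRS2 and MMACHC. PMVK and FOXO1 were named after their values were seen. Some genes that the rule selects are not reported here.

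Alternatives were pseudocounts of 0.5 and 10, no filter and a filter at a mean of 50, upper-quartile and total-count scaling, array weights, edgeR 4.0.16 quasi-likelihood and DESeq2 1.42.0 on the recovered reads, the replicate number as a block, and each library left out in turn. On recovered reads edgeR called 5853 genes and DESeq2 6258. Added after seeing the data were reads thinned to the smallest library, a fit without genes of within-group SD above 0.5 on log2(value + 10), and camera with a variance trend. Camera was run in both forms before the text was written, and the default form, which calls fewer lists, is the one reported. Other splits of the libraries were drawn 100 at a time with a fixed seed.

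The limma step was tested on simulated counts for this comparison, 16081 genes with 50 changed at each size, and called 42% of those changed 1.25-fold, 66% at 1.5-fold, 90% at 2-fold and 100% at 3-fold, with 0.0315% of unchanged genes called. The changed genes were drawn from those with a mean of 50 or more. Far fewer genes were changed than the 5879 called in the real data, so these percentages need not hold there. Transcript length, GC content and exon overlap came from GENCODE annotation of another build by Ensembl identifier, matched for 96.6% of genes tested, and no coordinates are printed.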

Results

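HepG2 cells, an established human liver cancer cell line, were transfected with a control siRNA or with siRNA against HCF-1, a chromatin-bound cofactor encoded by HCFC1 (gene identifier ENSG00000172534). RNA was sequenced in 8 cultures of each group, which the labels call biological replicates. The deposited table held 56969 Ensembl genes as normalized counts. Totals of recovered reads were 21030830 to 32820459 in the control libraries and 25098840 to 43186890 in the HCF-1 siRNA libraries, a difference with a two-sided exact permutation p of 0.0375. Values in parentheses after gene symbols are log2 fold changes of HCF-1 siRNA over control siRNA with their standard errors, on the log2(normalized count + 1) scale, 8 libraries against 8. Adjusted p-values for genes are from limma with Benjamini-Hochberg adjustment.

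HCFC1, the targeted gene, fell from 5631 ± 671 to 3682 ± 339.6 normalized counts (mean and SD, 8 libraries each), to 65.4% of the control mean. Control libraries ranged from 4851 to 6878 and HCF-1 siRNA libraries from 3112 to 4171, with no overlap. The log2 fold change was -0.61 ± 0.07 (SE; limma adjusted p = 4.52e-06). The two-sided exact permutation p was 1.55e-04, the smallest that 12870 splits can give.

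**Figure D1:**
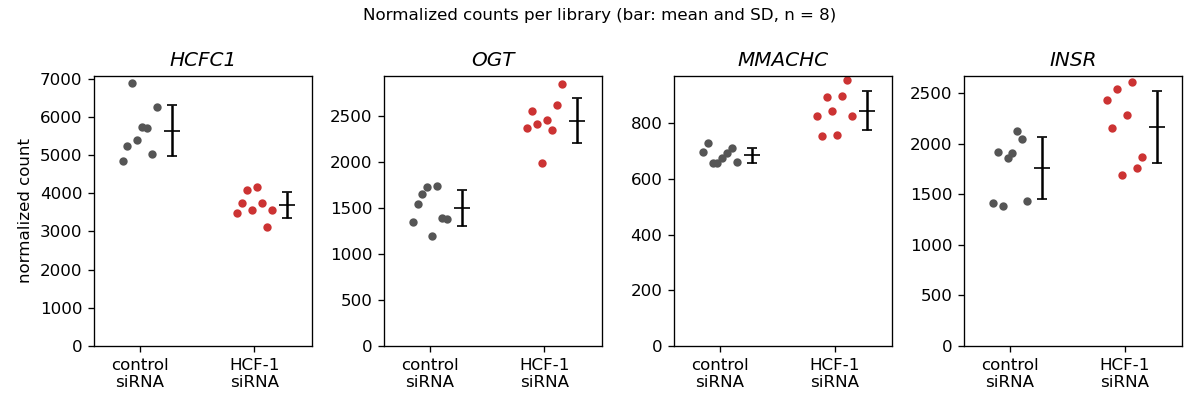
Normalized counts (y axes, from 0) of HCFC1, OGT, MMACHC and INSR in each control siRNA and HCF-1 siRNA library. Points are libraries, and bars give the mean and SD of 8 libraries. The HCFC1, OGT and MMACHC values of the groups do not overlap, while those of INSR do.

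Across 16081 genes tested, 5879 changed after HCF-1 siRNA, 2932 higher and 2947 lower. At least 1.5-fold changes were found for 1432 of them, 909 higher and 523 lower. The 2 groups' values did not overlap for 1579 genes, where chance gives 0.0155% of genes. Among called genes with a group mean of at least 100 and no overlap between the groups, the largest increases included ZFP37 (1.70 ± 0.10), a zinc finger gene, and TRMT10A (1.63 ± 0.27), a tRNA methyltransferase gene. The antisense RNA genes FBXL19-AS1 (2.01 ± 0.09) and STARD4-AS1 (1.76 ± 0.29) also rose, but the strand setting of the counting is not given in the sources used here, so reads of their opposite-strand partners cannot be separated from theirs. TBC1D3F (2.08 ± 0.37), GOLGA6L5P (1.84 ± 0.64), MST1L (1.66 ± 0.19) and the readthrough gene RTEL1-TNFRSF6B (1.59 ± 0.21) rose too, and reads shared with near-identical or overlapping genes make these values uncertain. The largest decreases under the same limits included PARD6A (-1.35 ± 0.15), a cell polarity gene, LCK (-1.30 ± 0.14), a kinase gene, S100A3 (-1.20 ± 0.13), MICB (-1.14 ± 0.25), TMEM261 (-1.08 ± 0.06) and C4orf48 (-1.02 ± 0.14). SLX1B (-2.18 ± 0.69), which has a near-identical copy, and the antisense gene LINC00094 (-1.05 ± 0.12) fell with the same uncertainty. Some called genes whose groups overlap had larger fold changes. MICB ran from 407.4 to 1615 normalized counts over the control libraries and from 325.3 to 384.8 over the HCF-1 siRNA libraries, so the size of its decrease is uncertain. The log2 fold change of SLX1B was -1.466 (adjusted p = 2.55e-04) without HCF-1 siRNA replicate 2, where it was listed at 0, and SLX1B lost its call in 1 of 27 alternatives (adjusted p 2.55e-04 to 0.067 over the alternatives). That of GOLGA6L5P was 1.155 (adjusted p = 5.75e-05) without control siRNA replicate 7, where it was listed at 0, and GOLGA6L5P lost its call in 5 of 27 alternatives, among them those without HCF-1 siRNA replicate 1, 2 or 4 (adjusted p 5.75e-05 to 0.0984 over the alternatives).

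Most genes of cholesterol synthesis rose after HCF-1 siRNA. MVD (1.06 ± 0.11), an enzyme of the mevalonate pathway, went from 1204 ± 179 to 2516 ± 405 normalized counts (adjusted p = 1.09e-06). MSMO1 (1.00 ± 0.08), an enzyme of a later step, went from 969 ± 135 to 1926 ± 145 normalized counts (adjusted p = 9.00e-08). Of 24 measured members, 21 rose, 1 fell and 2 did not pass, with a median log2 fold change of 0.48 (camera adjusted p = 1.02e-10, and adjusted p = 0.00518 with an estimated correlation), and adjusted over the list alone 21 rose and 1 fell. The member that fell was PMVK. INSIG1, a feedback regulator of the pathway, was listed at 0 to 6.82 normalized counts and was not tested; HepG2 cells usually express it and incomplete counting was not ruled out, so this is not a measure of absent expression.

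Among fatty acid and triglyceride synthesis genes, GPAM (0.95 ± 0.13), which starts glycerolipid synthesis, PNPLA3 (0.92 ± 0.12), a lipid droplet protein, and MLXIPL (0.89 ± 0.10), a carbohydrate-responsive transcription factor, rose. Of 23 measured members, 12 rose, 2 fell and 9 did not pass, with a median log2 fold change of 0.24 (camera adjusted p = 0.00418, and adjusted p = 0.0206 with an estimated correlation), and adjusted over the list alone 12 rose and 3 fell.

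Most proteasome subunits fell. PSMD13 (-0.45 ± 0.04) and PSMD2 (-0.42 ± 0.04) of the regulatory particle and PSMB2 (-0.39 ± 0.03) of the core fell, PSMD2 from 10027 ± 536 to 7489 ± 299 normalized counts. Of 31 measured members, 0 rose, 23 fell and 8 did not pass, with a median log2 fold change of -0.20 (camera adjusted p = 3.03e-10, and adjusted p = 0.00506 with an estimated correlation), and adjusted over the list alone 0 rose and 26 fell. Among oxidative phosphorylation subunits, NDUFA12 (-0.52 ± 0.09) and NDUFV1 (-0.42 ± 0.06) of complex I and COX8A (-0.40 ± 0.05) of cytochrome c oxidase fell. Of 76 measured members, 2 rose, 39 fell and 35 did not pass, with a median log2 fold change of -0.15 (camera adjusted p = 1.55e-07, and adjusted p = 0.0796 with an estimated correlation), and adjusted over the list alone 6 rose and 45 fell. The mitochondrial ribosomal protein genes MRPL55 (-0.56 ± 0.09), MRPS12 (-0.53 ± 0.07) and MRPL41 (-0.47 ± 0.06) fell. Of 77 measured members, 11 rose, 26 fell and 40 did not pass, with a median log2 fold change of -0.06 (camera adjusted p = 0.0326, and adjusted p = 0.263 with an estimated correlation), and adjusted over the list alone 11 rose and 27 fell. The call was also lost with the filter at a mean of 50, the replicate block and without control siRNA replicate 2 or HCF-1 siRNA replicate 6.

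Of the replication genes, more fell than rose, among them GINS2 (-0.54 ± 0.04) and GINS4 (-0.42 ± 0.10) of the GINS complex and TK1 (-0.45 ± 0.06), thymidine kinase. Of 45 measured members, 3 rose, 20 fell and 22 did not pass, with a median log2 fold change of -0.15 (camera adjusted p = 3.26e-04, and adjusted p = 0.0295 with an estimated correlation), and adjusted over the list alone 4 rose and 24 fell. Of the p53 target genes 13 rose and 0 fell, with ZMAT3 (0.77 ± 0.05), POLH (0.66 ± 0.10), a translesion polymerase, and SESN1 (0.59 ± 0.06) the members of largest change. Of 26 measured members, 13 rose, 0 fell and 13 did not pass, with a median log2 fold change of 0.19 (camera adjusted p = 2.83e-04, and adjusted p = 0.0206 with an estimated correlation), and adjusted over the list alone 14 rose and 0 fell. Mitosis genes went both ways, as HMMR (0.52 ± 0.10) and CENPE (0.75 ± 0.21) rose and CDC25B (-0.49 ± 0.09) fell. Of 42 measured members, 9 rose, 9 fell and 24 did not pass, with a median log2 fold change of -0.01 (camera adjusted p = 0.792, and adjusted p = 0.889 with an estimated correlation), and adjusted over the list alone 9 rose and 9 fell.

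Among genes of secreted liver proteins, ITIH3 (0.70 ± 0.06), F5 (0.67 ± 0.08), coagulation factor V, and APOH (0.64 ± 0.07) rose, the last from 26903 ± 2469.9 to 41944 ± 4468 normalized counts. Of 34 measured members, 24 rose, 3 fell and 7 did not pass, with a median log2 fold change of 0.24 (camera adjusted p = 1.15e-06, and adjusted p = 0.107 with an estimated correlation), and adjusted over the list alone 24 rose and 4 fell. The epithelial markers KRT23 (-0.60 ± 0.06), KRT19 (-0.55 ± 0.05) and SOX4 (-0.36 ± 0.05) fell. Of 9 measured members, 2 rose, 6 fell and 1 did not pass, with a median log2 fold change of -0.34 (camera adjusted p = 0.0276, and adjusted p = 0.0664 with an estimated correlation), and adjusted over the list alone 2 rose and 6 fell. Without a filter on low values, where members of low counts join the list, the median was -0.113 (camera adjusted p = 0.0326), and the call was lost with the filter at a mean of 50 and with the replicate block. In the integrated stress response, ALDH1L2 (1.36 ± 0.25), DDIT3 (0.75 ± 0.07) and NUPR1 (0.62 ± 0.08) rose. Of 25 measured members, 11 rose, 2 fell and 12 did not pass, with a median log2 fold change of 0.08 (camera adjusted p = 0.0418, and adjusted p = 0.0813 with an estimated correlation), and adjusted over the list alone 11 rose and 2 fell. The call was also lost with the filter at a mean of 50, the replicate block, total-count scaling (median 0.0558) and without control siRNA replicate 1 or 8 or HCF-1 siRNA replicate 3 or 6.

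Among genes of proteins known to work with HCF-1, more rose than fell. PPARGC1A (1.32 ± 0.18), a metabolic coactivator, CREBZF (0.82 ± 0.08) and OGT (0.71 ± 0.08), the transferase that glycosylates and cleaves HCF-1, rose. OGT went from 1499.5 ± 198 to 2453 ± 247 normalized counts (adjusted p = 3.64e-06). HCFC2 (0.55 ± 0.18), the paralog of HCFC1, rose (adjusted p = 0.0243), as did ZNF143 (0.38 ± 0.13) (adjusted p = 0.0314). HCFC2 lost its call in 3 of 28 alternatives, among them those without HCF-1 siRNA replicate 2 or 4 (adjusted p 0.0078 to 0.0515 over the alternatives). ZNF143 lost its call in 9 of 28 alternatives, among them those without control siRNA replicate 1, 2, 3 or 6 or HCF-1 siRNA replicate 2, 5 or 8 (adjusted p 0.00275 to 0.0629 over the alternatives). THAP11 (-0.01 ± 0.04), GABPA (0.16 ± 0.08) and BAP1 (-0.10 ± 0.07) did not pass. Of 39 measured members, 16 rose, 2 fell and 21 did not pass, with a median log2 fold change of 0.14 (camera adjusted p = 0.00353, and adjusted p = 0.015 with an estimated correlation), and adjusted over the list alone 16 rose and 3 fell. MMACHC, a known HCF-1 target in cobalamin metabolism, went from 685 ± 26.7 to 845 ± 70 normalized counts, a log2 fold change of 0.30 (adjusted p = 3.62e-04). Of 14 measured members, 5 rose, 3 fell and 6 did not pass, with a median log2 fold change of 0.10 (camera adjusted p = 0.483, and adjusted p = 0.532 with an estimated correlation), and adjusted over the list alone 5 rose and 3 fell. That median ranged from 0.0339 to 0.169 with 1 library left out.

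The series title concerns the insulin receptor. INSR (0.30 ± 0.11) passed narrowly (adjusted p = 0.0472), from 1760.3 ± 302 to 2167 ± 358 normalized counts. INSR lost its call in 14 of 28 alternatives, among them those without control siRNA replicate 1, 3, 4 or 8 or HCF-1 siRNA replicate 1, 2, 3, 5 or 6 (adjusted p 0.0239 to 0.0917 over the alternatives). IGF1R (0.07 ± 0.08) and IRS1 (0.16 ± 0.08) did not pass, and leaving out 1 library gave 0.04 to 0.12 for IGF1R. IRS2 was listed at 0 to 10.9 normalized counts and was not tested, and for the same reason as for INSIG1 this is not a measure of absent expression. In the insulin signalling list RICTOR (0.55 ± 0.10) and TSC1 (0.53 ± 0.06) rose and RPS6KB2 (-0.52 ± 0.07) fell. Of 41 measured members, 8 rose, 9 fell and 24 did not pass, with a median log2 fold change of -0.05 (camera adjusted p = 0.592, and adjusted p = 0.564 with an estimated correlation), and adjusted over the list alone 8 rose and 9 fell. With 1 library left out the median ranged from -0.0657 to -0.0212, never called. FOXO1, a member that did not pass (0.16 ± 0.45), varied widely within both groups. It was among the 161 genes, described below, that jumped between libraries of one group, so a counting effect was not ruled out. It ran from 398.8 to 3183 normalized counts in control and from 419.7 to 2877 in HCF-1 siRNA libraries, so a change in FOXO1 may have been missed. Of the gluconeogenesis and FOXO target genes, G6PC (0.78 ± 0.19), PCK1 (0.74 ± 0.12) and TAT (0.60 ± 0.11) rose. Of 12 measured members, 6 rose, 1 fell and 5 did not pass, with a median log2 fold change of 0.28 (camera adjusted p = 0.0546, and adjusted p = 0.12 with an estimated correlation), and adjusted over the list alone 6 rose and 1 fell. This list missed the threshold.

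The other 13 lists measured were not called by camera. For glycolysis, 6 of 23 rose and 11 fell (6 and 11 adjusted over the list alone, camera adjusted p = 0.191), with PFKP (-0.91 ± 0.13) and PFKFB3 (0.99 ± 0.36) among those that passed. For fatty acid oxidation, 7 of 27 rose and 1 fell (6 and 0 adjusted over the list alone, camera adjusted p = 0.202), with ACADSB (0.37 ± 0.05) among those that passed. For cytosolic ribosomal proteins, 23 of 79 rose and 11 fell (24 and 12 adjusted over the list alone, camera adjusted p = 0.191), with RPL28 (-0.30 ± 0.05) and RPS2 (-0.31 ± 0.06) among the fewer that fell. For translation factors, 12 of 42 rose and 12 fell (12 and 15 adjusted over the list alone, camera adjusted p = 0.415), with EIF4A2 (0.67 ± 0.06) and EIF2B1 (-0.44 ± 0.06) among those that passed. For ribosome biogenesis, 6 of 37 rose and 12 fell (6 and 13 adjusted over the list alone, camera adjusted p = 0.389), with UTP20 (0.46 ± 0.06) and NHP2 (-0.47 ± 0.06) among those that passed. For endoplasmic reticulum chaperones, 3 of 22 rose and 6 fell (3 and 6 adjusted over the list alone, camera adjusted p = 0.465), with HERPUD1 (0.37 ± 0.04) and HYOU1 (-0.28 ± 0.06) among those that passed. For hepatocyte transcription factors, 6 of 19 rose and 0 fell (6 and 0 adjusted over the list alone, camera adjusted p = 0.168), with PROX1 (0.48 ± 0.06) among those that passed. For interferon response, 0 of 23 rose and 5 fell (0 and 4 adjusted over the list alone, camera adjusted p = 0.168), with ISG15 (-0.70 ± 0.10) and IFITM3 (-0.42 ± 0.05) among those that passed. For NF-kB and acute phase, 3 of 12 rose and 2 fell (3 and 2 adjusted over the list alone, camera adjusted p = 0.171), with TNFAIP3 (0.56 ± 0.07) and SOCS3 (-0.69 ± 0.18) among those that passed. For immediate early genes, 1 of 18 rose and 0 fell (1 and 0 adjusted over the list alone, camera adjusted p = 0.699), with CTGF (0.31 ± 0.05) among those that passed. For mesenchymal markers, 0 of 8 rose and 2 fell (0 and 2 adjusted over the list alone, camera adjusted p = 0.389), with TAGLN (-0.83 ± 0.07) and COL1A1 (-0.56 ± 0.15) among those that passed. For blood cell markers, 0 of 7 rose and 2 fell (0 and 1 adjusted over the list alone, camera adjusted p = 0.202), with LAPTM5 (-0.32 ± 0.08) among those that passed. For endothelial markers, 0 of 7 rose and 2 fell (0 and 2 adjusted over the list alone, camera adjusted p = 0.336), with ESAM (-0.89 ± 0.13) among those that passed. PFKFB3 lost its call in 10 of 27 alternatives, among them those without control siRNA replicate 1, 7 or 8 or HCF-1 siRNA replicate 2, 4, 5, 6 or 7 (adjusted p 0.021 to 0.116 over the alternatives). CCL20, a chemokine gene of the NF-kB list, rose from 522 ± 33.1 to 1384 ± 140.0 normalized counts (adjusted p = 1.84e-10). The 13 genes of the mitochondrially encoded list were not found in the deposited table by symbol, so that list had 0 measured members.

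**Figure D2:**
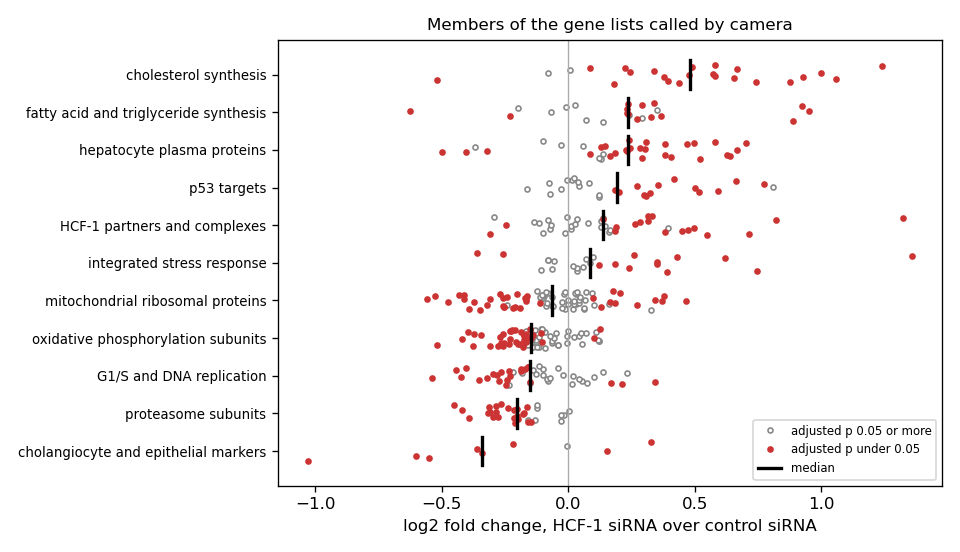
Log2 fold changes of HCF-1 siRNA over control siRNA (x axis) for the members of the 11 lists called by camera with the preset correlation. Filled points passed the limma test, open points did not, and black bars are list medians, which run from -0.34 for cholangiocyte and epithelial markers to 0.48 for cholesterol synthesis.

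In all, 11 of 28 lists were called, 6 higher and 5 lower, and 6 of them held with an estimated correlation. The number of lists called was matched by other splits of the 16 libraries, where 5 of 100 splits, the real one included, called as many. The 4 others kept 6 libraries of one group on one side, so part of the group difference remained in them. The 34 splits with 4 and 4, which hold no net difference between the siRNA groups, still called up to 3 lists with at most 1 gene changed. Camera p-values at the preset correlation may therefore be too small.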

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

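In 10 of 208 groups of named gene values and 1 of 36 groups of library measures, 1 library lay apart from the other 7 of its group, judged by its gap to the nearest library over the range of the group. About 1 in 20 groups is picked by chance. KRT23 had 3771 normalized counts in HCF-1 siRNA replicate 5, against 2650.0 to 3177. PPARGC1A had 1739.8 normalized counts in HCF-1 siRNA replicate 6, against 912 to 1276. CTGF had 12182 normalized counts in HCF-1 siRNA replicate 5, against 9427 to 10237. ZFP37 had 75.4 normalized counts in control siRNA replicate 6, against 55.1 to 63.7. GABPA had 788 normalized counts in HCF-1 siRNA replicate 8, against 549 to 632. HK1 had 136 normalized counts in HCF-1 siRNA replicate 4, against 17.3 to 70. RPS6KB2 had 1499 normalized counts in HCF-1 siRNA replicate 3, against 1136 to 1284. GOLGA6L5P had 0 normalized counts in control siRNA replicate 7, against 33.8 to 58.2. LINC00094 had 545 normalized counts in control siRNA replicate 7, against 279.6 to 346. FBXL19-AS1 had 308 normalized counts in HCF-1 siRNA replicate 2, against 353 to 388. The share of reads on miscellaneous RNAs was 0.00432% in control siRNA replicate 1, against 0.00237% to 0.00292% in the others.

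The test of overlap and the test of counting noise were chosen after the pattern was seen. Among 11469 genes with a mean of 100 or more, 161 jumped between libraries of one group (within-group SD above 0.75 on log2(value + 10)), GLUD1P2 (14.3 to 2171 normalized counts over the control libraries) and LINC01138 (0 to 1132 normalized counts over the control libraries) among them as examples chosen after their values were seen, and 22 of these were called. Reads split between overlapping genes on one strand do not account for most of those that could be assessed, since of the 145 with annotation 20% (exact 95% binomial interval 13.8% to 27.4%) overlap an expressed gene, against 8.45% of other genes. Counting noise is argued against by the 8 with a mean of 1000 or more. Other counting effects stay open, and no biological explanation was tested.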

How the results depend on the processing

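The alternatives with thinned reads, without the 1610 genes of within-group SD above 0.5 on log2(value + 10) and with a camera variance trend were chosen after seeing the data. Genes changed ranged from 5163 to 6258 over 28 alternatives, genes higher from 2585 to 3160 and lower from 2500 to 3395. Total-count scaling gave 2585 higher and 3395 lower (43.2% higher, against 49.9%). HCFC1 kept its direction and call in all 28, from -0.64 to -0.57. Genes changed at least 1.5-fold numbered 897 with the filter at a mean of 50, where fewer genes are tested, against 1432. Of 104 named genes, 9 lost their call in at least 1 alternative, 1 gained one and 1, THAP11, turned direction without a call (0.00419 without HCF-1 siRNA replicate 1, range -0.0243 to 0.00419 with 1 library left out and -0.0398 to 0.00419 over all alternatives).

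List values are median log2 fold changes. With the filter at a mean of 50, mitochondrial ribosomal proteins at -0.0647 (adjusted p = 0.0604), integrated stress response at 0.084 (adjusted p = 0.0537) and cholangiocyte and epithelial markers at -0.28 (adjusted p = 0.0604) lost their calls, and mesenchymal markers, never called, turned to 0.0282 (adjusted p = 0.498). Without a filter the cholangiocyte and epithelial markers, still called, were at -0.113 (adjusted p = 0.0326), with members of low counts included. Total-count scaling left integrated stress response at 0.0558 (adjusted p = 0.0653). With an estimated correlation the calls were lost for mitochondrial ribosomal proteins at -0.0647 (adjusted p = 0.263), oxidative phosphorylation at -0.149 (adjusted p = 0.0796), integrated stress response at 0.084 (adjusted p = 0.0813), plasma proteins at 0.236 (adjusted p = 0.107) and cholangiocyte and epithelial markers at -0.341 (adjusted p = 0.0664). Gluconeogenesis and FOXO targets gained a call without a filter at 0.282 (adjusted p = 0.0366), with edgeR at 0.271 (adjusted p = 0.0364), DESeq2 at 0.281 (adjusted p = 0.0429), thinned reads at 0.281 (adjusted p = 0.0488) and the variance trend at 0.282 (adjusted p = 0.049984). NF-kB and acute phase gained one with edgeR at 0.137 (adjusted p = 0.0239) and DESeq2 at 0.148 (adjusted p = 0.0214). Leaving out 1 library gave 0.252 to 0.305, adjusted p 0.0431 to 0.0855 for gluconeogenesis (called without control siRNA replicates 4, 5 or 7 or HCF-1 siRNA replicates 1, 5 or 8), 0.061 to 0.108, adjusted p 0.026 to 0.0685 for the stress response (lost without control siRNA replicates 1 or 8 or HCF-1 siRNA replicates 3 or 6), -0.0761 to -0.0583, adjusted p 0.0175 to 0.0518 for mitochondrial ribosomal proteins (lost without control siRNA replicate 2 or HCF-1 siRNA replicate 6) and -0.0273 to 0.0138, adjusted p 0.634 to 0.973 for G2/M and mitosis. The causes were not tested. With reads thinned to the smallest library 5733 genes changed, 5544 of them also called with all reads.

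The replicate numbers showed no sign of pairing the libraries. Same-number correlations ran from -0.07 to 0.10, and 1 of 8 control libraries correlated best with its own number. A weak effect shared by number cannot be excluded in this way. The highest correlation between the groups was 0.20, of control siRNA replicate 6 with HCF-1 siRNA replicate 3. With the replicate block 5484 genes changed, and the calls of mitochondrial ribosomal proteins at -0.0647 (adjusted p = 0.0526), integrated stress response at 0.084 (adjusted p = 0.0526) and cholangiocyte and epithelial markers at -0.341 (adjusted p = 0.0526) were lost.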

Other observations

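The gene families, biotypes and camera tests of this paragraph and the next were chosen after the data were seen, with adjustment over 24 sets. Of 16 families, 9 were called and 7 were not (claudins, SR splicing factors, HNRNP, chaperonins, histones, deubiquitinases and lysine demethylases and methyltransferases, adjusted p 0.0799 to 0.837), and 8 of the 9 were called with an estimated correlation. For tubulin genes, 1 of 18 rose and 10 fell (median -0.36, adjusted p = 3.08e-05, and adjusted p = 0.036 with an estimated correlation), including TUBA1A (-1.01 ± 0.08) and TUBB2B (-0.89 ± 0.08). For keratin genes, 0 of 21 rose and 11 fell (median -0.52, adjusted p = 2.15e-06, and adjusted p = 0.036 with an estimated correlation), including KRT8 (-0.52 ± 0.04) and KRT18 (-0.47 ± 0.05), the main keratins of simple epithelia. For S100 genes, 0 of 10 rose and 7 fell (median -0.39, adjusted p = 3.08e-05, and adjusted p = 0.0634 with an estimated correlation), including S100A11 (-0.76 ± 0.06) and S100A6 (-0.62 ± 0.10). For genes that host small nucleolar RNAs, 6 of 14 rose and 0 fell (median 0.26, adjusted p = 0.00709, and adjusted p = 0.0251 with an estimated correlation), including SNHG1 (0.77 ± 0.10). For zinc finger genes, 109 of 480 rose and 35 fell (median 0.10, adjusted p = 0.00716, and adjusted p = 0.0061 with an estimated correlation). For cytochrome P450 genes, 9 of 31 rose and 2 fell (median 0.41, adjusted p = 0.00716, and adjusted p = 0.036 with an estimated correlation). For metallothionein genes, 0 of 8 rose and 4 fell (median -0.39, adjusted p = 0.00709, and adjusted p = 0.036 with an estimated correlation). For mitochondrial import genes, 1 of 25 rose and 11 fell (median -0.21, adjusted p = 0.00276, and adjusted p = 0.0251 with an estimated correlation). For protocadherin genes, 0 of 18 rose and 6 fell (median -0.38, adjusted p = 0.00709, and adjusted p = 0.0251 with an estimated correlation). Families were matched by symbol, pseudogenes included, and reads shared between similar members make single members uncertain. Such reads could also repeat a change over several members, which would make the counts and p-values of a family look stronger. The medians of these 9 families kept their sign with total-count and upper-quartile scaling.

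The protein-coding biotype, which holds most genes tested, was called lower relative to the other genes tested. Of its 13162 genes, 2380 rose and 2733 fell (median -0.007, camera adjusted p = 0.0172, and adjusted p = 3.65e-04 with an estimated correlation). Most of the other genes belong to the biotypes below, so this call largely mirrors theirs. It does not show that protein-coding genes fell as a whole. Among biotypes other than protein-coding the calls differed. For lincRNA genes, 143 of 697 rose and 55 fell (median 0.14, adjusted p = 0.0157, and adjusted p = 0.036 with an estimated correlation). For processed transcripts, 51 of 201 rose and 11 fell (median 0.14, adjusted p = 0.015, and adjusted p = 0.0357 with an estimated correlation). For sense-intronic genes, 15 of 65 rose and 1 fell (median 0.28, adjusted p = 0.00221, and adjusted p = 0.0575 with an estimated correlation). For sense-overlapping genes, 9 of 46 rose and 2 fell (median 0.21, adjusted p = 0.0185, and adjusted p = 0.114 with an estimated correlation). The antisense biotype was not called: 148 of 914 rose and 81 fell (median 0.08, adjusted p = 0.17, and adjusted p = 0.0965 with an estimated correlation). The pseudogene biotype was not called either: 174 of 943 rose and 56 fell (median 0.03, adjusted p = 0.0862, and adjusted p = 0.0965 with an estimated correlation). Shares of all reads, not tested between groups, went from control to HCF-1 siRNA libraries as follows (mean and SD, 8 libraries each). The share of antisense genes went from 0.531% ± 0.00828 to 0.515% ± 0.00909, that of lincRNA genes from 0.305% ± 0.00955 to 0.338% ± 0.0125, that of processed transcripts from 0.305% ± 0.0114 to 0.335% ± 0.00826 and that of sense-intronic genes from 0.0179% ± 0.00357 to 0.0227% ± 0.00522. The pseudogene share went from 1.88% ± 0.125 to 2.4% ± 0.191, with a control range of 1.75% to 2.12% and an HCF-1 siRNA range of 2.14% to 2.66%.

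The 5 biotypes above other than protein-coding and pseudogenes were pooled after their values were seen. The median log2 fold change over their 1923 genes was 0.12. It was 0.095 over 2866 genes with pseudogenes included, which the tests below left out. The groups differed in depth, but with reads thinned to the smallest library the median was 0.117 (95% bootstrap interval 0.0956 to 0.144), which argues against depth as the cause. For the 90.4% of these genes with a GC content and transcript length, it went from 0.106 to 0.0624 (95% bootstrap interval 0.038 to 0.0951) on removing a trend on both, so a part played by these cannot be told apart at the bounds set. A larger share of nuclear RNA in the HCF-1 siRNA libraries is a candidate explanation: of 14 measured nuclear-retained and intron-detaining transcripts, listed before their values were seen but after CCNL2 and RBM39 had been, 13 rose, with a median of 0.819 (95% bootstrap interval 0.524 to 1.03) and a camera adjusted p = 2.03e-09 (adjusted p = 0.00712 with an estimated correlation), among them CLK1 (1.06 ± 0.09), CCNL1 (1.02 ± 0.11) and KCNQ1OT1 (0.99 ± 0.13). A response of these transcripts to the HCF-1 siRNA itself would look alike and stays open.

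For the lower oxidative phosphorylation and proteasome lists, GC content and transcript length are argued against as the whole cause, since after removing that trend the medians were -0.159 (95% bootstrap interval -0.192 to -0.106) and -0.257 (95% bootstrap interval -0.289 to -0.198). Depth is argued against as well, with thinned medians of -0.149 (95% bootstrap interval -0.169 to -0.121) and -0.209 (95% bootstrap interval -0.271 to -0.168). An effect of lower HCFC1 expression stays open. The only comparison, of HCF-1 siRNA with control siRNA, cannot separate it from other differences between the groups. The oxidative phosphorylation call is lost with an estimated correlation (camera adjusted p = 0.0796).

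Among 100 splits of the 16 libraries into 8 and 8, the real one included, 1 gave as many genes changed (5879, highest other 2645), 1 as many higher (2932, highest other 1363), 1 as many lower (2947, highest other 1363) and 1 as many changed at least 1.5-fold (1432, highest other 583). This argues against chance as the source of these counts, which come from the same fit. Such splits cannot separate the siRNA from another difference that follows the groups. For the number of lists called, 5 of the 100 splits gave as many as the real 11, with 13 the highest other. That count does not exclude chance, but it cannot decide the question either, since the other splits that reached it kept part of the group difference. Whether the retained difference raised their counts was not tested. The 4 splits that kept 7 libraries of one group on one side called at most 10 lists. The splits with most genes kept 7 libraries of one group on one side, and the 4 other splits with 11 or more lists, 13 in 2 of them, kept 6 and called 0 genes. The 34 splits with 4 and 4 called at most 3 lists and the 51 with 5 and 3 at most 9, with at most 1 gene changed in either. Camera at the preset correlation thus called lists where at most 1 gene changed, so its p-values may be too small.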
